A study of Homo sapiens with 15 samples.

How the data were processed

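The series holds 15 libraries of the LHCN-M2-iDUX4 myoblast line after 6 h with 0 or 250 ng/ml of doxycycline: 6 RNA libraries, 3 per dose, and 9 chromatin immunoprecipitation libraries, 1 per antibody and dose. Groups were taken from the labels. The RNA libraries were made with a stranded poly(A) kit and sequenced from both ends, per the labels' protocols. Input, H3 and H3K4me3 libraries were not analysed here. Peak lists were assigned to libraries by the antibody and dose in their names.

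Reads were trimmed with Trimmomatic 0.32 and handled with SAMtools 1.0, per the submitters' processing notes. RNA reads were aligned with STAR 2.4.2a to hg19 and compared with DESeq2 1.8.2, and immunoprecipitated reads were aligned with Bowtie2 2.2.4 to hg19 and peaks called with MACS 1.4, per the submitters' processing notes. The gene annotation, the read counter and the control library for peak calling are not stated. The authors deposited FPKM values, fragments per kilobase of gene and per library total, for 64102 Ensembl genes in each RNA library, with no value column unmatched to a library. The authors' deposited table gives a mean signal in normalised reads, a log2 fold change with its standard error, a Wald score, a p-value and an adjusted p-value for 18657 genes, and classes of distance from the gene to a DUX4 peak and of DNase overlap of that peak. Whether that fold change was shrunken is not stated. The deposited peak files give a score that, by the layout of MACS 1.4, grows with the negative log10 of the p-value, and the deposited summit file a signal, the number of reads piled up at the summit. The lowest score in each list was about 50, and the DUX4 summits had a median height of 15 reads. Positions are printed counted from 1 in hg19.

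Read numbers were recovered from the FPKM and the mean signal of the authors' table. Of recovered values between 1 and 50 reads, 100% were whole within 0.02 in each library, and the libraries held 27417323 to 33071808 recovered reads. These reads have no molecular identifiers.

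Expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust) on log2(FPKM + 0.5) over the 12289 genes with a mean FPKM of at least 0.5. Genes were called with a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 1 on the log2 scale. List members were counted by the adjusted p alone, both over all genes tested and adjusted over the list alone. The 16 gene lists hold DUX4 target genes, myogenic regulators and muscle structural genes, p53 targets and apoptosis genes, NRF2 and oxidative stress genes, unfolded protein and integrated stress response genes, heat shock genes, immediate early genes, cell cycle genes, replication-dependent histone genes, histone acetyltransferases, deacetylases and bromodomain genes, nonsense-mediated decay genes, interferon-stimulated genes, NF-kB and inflammatory cytokine genes, extracellular matrix and fibroblast markers, markers of other cell types, and mitochondrially encoded genes. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the lists. Every camera call on the lists was lost with an estimated correlation. As an alternative limma's fry tests whether a list's genes move, on balance, one way, and does not compare the list with other genes. Of 66 names of DUX4 target genes 61 were found in the table. Adjusted p-values in the text are limma's unless credited to the authors' table.

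The tests, lists, thresholds and most alternatives were fixed before the data were examined. By the rule for named genes fixed then, the text names the DUX4 and DUX4-like rows past the filter, the 10 largest rises and 10 largest falls among called genes with a symbol, a mean of at least 1 FPKM in the higher group and no overlap between the libraries of the groups, up to 4 members past the test per list with the largest change (or, with none past it, the 2 with the highest level), EP300 and CREBBP, and the 5 DUX4 peaks with the highest score. A part of the rule that needed gene starts in hg19 was not applied, since no hg19 annotation was used here. For the same reason expression by promoter H3K27ac was not analysed here, and the planned distance of gene starts to DUX4 summits was replaced by the authors' distance classes after the data were seen. Members of gene groups added after the values were seen are named only in the closing section.

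Peaks were compared with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and intervals and Fisher's exact tests (two-sided) computed with scipy 1.17.1 at 95%, by the exact binomial method for shares. H3K27ac peaks of the doses were called overlapping from 1 bp. DUX4 summits were placed in H3K27ac peaks, beside the mean of 6 sets of summits displaced by 50, 100 and 200 kb in both directions. Figures were drawn with matplotlib 3.10.9. No test between doses was run on peaks, since each has 1 library.

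Alternatives were pseudocounts of 0.1 and 1, no filter and a mean FPKM of at least 2, median-of-ratios rescaling, the replicate number as a block, eBayes without trend and robust, each library left out in turn, no fold minimum, camera with an estimated correlation, fry, a peak score of at least 100, equal numbers of H3K27ac peaks, overlap over at least 50% of the smaller peak, the whole DUX4 peak and random placement of summits in 100 draws. Added after the data were seen were voom on recovered reads, other distance classes, equal covered length, windows of 1 kb at peak midpoints, the profile up to 3 kb from the summit and windows of 500 bp on each side. Equal covered length kept all doxycycline H3K27ac peaks and only the highest-scoring untreated ones, 25868 of 136827, up to the same summed length.

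The expression test was tested on simulated data of 12253 tested genes. For genes higher or lower after doxycycline, of genes changed 2-fold 92% passed the adjusted p and 38% the fold minimum too, of genes changed 4-fold 100% and 94%, and of 12054 unchanged genes 1 was called. All simulated genes had the same dispersion, while genes in the data differ in spread, with ID1 at 13.1 ± 8.75 FPKM after doxycycline. These shares may therefore not hold for genes with a wide spread. Camera gave a p under 0.05 for 1 of 200 unchanged lists. The simulated genes were drawn independently, so this does not check lists whose genes vary together. In the data the estimated correlation was 0.444 for DUX4 target genes and 0.567 for immediate early genes. Overlaps of 9000 simulated intervals were checked against a direct count with 0 mismatches.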

Results

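The study used LHCN-M2-iDUX4, a derivative of the immortalized human myoblast line LHCN-M2 in which doxycycline switches on a tagged copy of DUX4, the double-homeobox transcription factor whose misexpression underlies facioscapulohumeral muscular dystrophy. Cells received 0 or 250 ng/ml of doxycycline for 6 h. RNA was sequenced in 3 libraries per dose, labelled as triplicates, while the series design counts 2 biological samples, so the triplicates may come from 1 culture per dose. Each p-value therefore measures the spread between these libraries. Chromatin immunoprecipitation gave 1 library per antibody and dose, and the H3K27ac lists of both doses and the list of tagged DUX4 after doxycycline were compared. H3K27ac is the acetylation of histone H3 at lysine 27, a mark of active enhancers and promoters. The RNA libraries held 27417323 to 30620461 recovered reads each without doxycycline and 31293923 to 33071808 with it. No line without the DUX4 construct was given doxycycline, so each difference below is between doxycycline and none.

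The first question was which genes changed within 6 h of induction. ZSCAN4 and DUXA were among the genes that rose most, and MYOD1 and ID1 among those that fell most. ZSCAN4 (ENSG00000180532), a zinc finger gene active in early embryos, rose from 6.19 ± 0.71 to 403 ± 58.6 FPKM (SD, n = 3 libraries each), a log2 change of 5.91 (limma adjusted p = 4.4e-06). DUXA, a related double-homeobox gene, rose from 1.66 ± 0.06 to 60.1 ± 9.19 FPKM. MYOD1, the master regulator of the muscle lineage, fell from 49.4 ± 1.72 to 6.42 ± 3.05 FPKM, a log2 change of -2.94 (limma adjusted p = 0.0010). ID1, an inhibitor of basic helix-loop-helix factors, fell from 172 ± 4.07 to 13.1 ± 8.75 FPKM, a log2 change of -3.84 (limma adjusted p = 0.0014).

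Log2 changes are of FPKM + 0.5, which shrinks changes from levels near 0, and the order of the genes depends on it. On that scale the other genes among the 10 largest rises were PRELID3BP4 (0.443 to 122 FPKM, log2 7.05), ZSCAN5CP (log2 5.01), ZNF705G (0.134 to 19.2 FPKM, log2 4.94), ZNF705E (log2 4.89), LINC01602 (log2 4.80), OSR2 (0.125 to 15.1 FPKM, log2 4.63), RFPL4B (5.22 to 141 FPKM, log2 4.63) and ZNF705A (log2 4.54). LINC01602 rose 27.95-fold on that scale and 453-fold by the ratio of mean FPKM. PRELID3BP4, ZSCAN5CP and the ZNF705 genes belong to families of similar copies, and how reads that fit several copies were counted is not stated, so their separate levels are uncertain. The other genes among the 10 largest falls were ID3 (125 to 13.0 FPKM, log2 -3.34), DUSP1 (log2 -3.14), KLF10 (28.9 to 3.19 FPKM, log2 -3.07), FOSL1 (113 to 15.0 FPKM, log2 -2.96), GADD45B (log2 -2.92), BHLHE40 (log2 -2.90), SOCS3 (11.1 to 1.19 FPKM, log2 -2.80) and EDN1 (50.2 to 7.31 FPKM, log2 -2.78). KLF10 is a transcription factor gene induced by TGF-beta, DUSP1 encodes a phosphatase of MAP kinases, and SOCS3 encodes an inhibitor of cytokine signalling. For the genes that fell, the third doxycycline library lay nearest to the untreated libraries, with ID1 at 8.44, 7.75 and 23.2 FPKM in the doxycycline libraries.

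**Figure D1:**
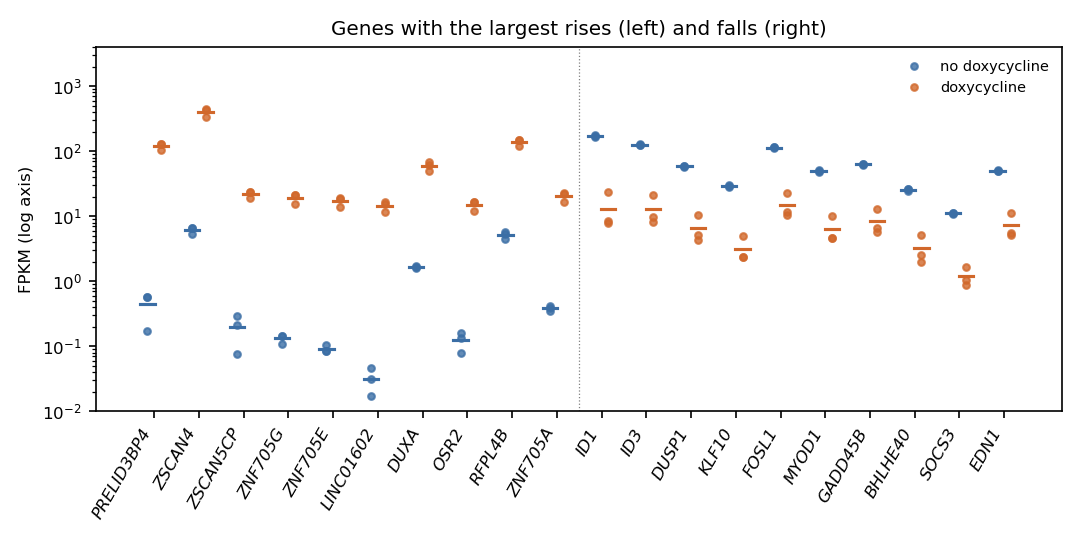
FPKM of the 10 genes with the largest rises and the 10 with the largest falls (log axis), with 1 point per library and a line at the mean of 3 libraries. ZSCAN4 rose from a mean of 6.19 to 403 FPKM and ID1 fell from 172 to 13.1 FPKM.

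Of 12289 genes tested, 312 rose and 249 fell at least 2-fold with a limma adjusted p under 0.05. Of these, 97 rose and 36 fell more than 4-fold, and 15 rose more than 16-fold. Without a fold minimum 2834 genes rose and 3389 fell. With a mean FPKM of at least 2 the number that rose was 187, and with voom on recovered reads, a test chosen after the data were seen, 394 genes fell. Voom gave larger log2 changes for LINC01602 (8.55), ZNF705E (7.47), PDGFRA (5.07), IFIH1 (1.61), BIRC3 (-1.50), KRT18 (-0.36) and BBC3 (-2.58, and -2.09 with a pseudocount of 0.1). The median log2 change over all genes tested was -0.01. Pearson's r across genes was 0.994 to 0.995 between libraries of the same dose and 0.952 to 0.968 between doses, and genes are not independent replicates.

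The DUX4 row was 0 FPKM in 5 of the 6 libraries and 0.015 FPKM in the second doxycycline library, so it does not show the induction. Of 17 DUX4 and DUX4-like rows, 10 were listed at 0 in all 6 libraries. DUX4L50, a DUX4-like pseudogene and the only such row above the filter, was at 2.73 ± 0.32 FPKM without and 3.05 ± 0.06 FPKM with doxycycline, a log2 difference of 0.14 that did not pass the test (limma adjusted p = 0.153) and was 0.0573 without the second untreated library.

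Most known DUX4 target genes that were measured rose. Of 31 measured members of that list, 27 rose, none fell and 4 did not pass the test, with a median log2 change of 1.18; ZSCAN4, ZNF705G, DUXA and RFPL4B changed most. Adjusted over the list alone, 27 rose and none fell. The list stood above the other genes in limma's camera test with a preset correlation (adjusted p = 1.5e-15; adjusted p = 0.307 with an estimated correlation). The median was 0.67 with no filter (52 members), 3.06 with a mean FPKM of at least 2 (20 members) and 1.99 with voom. A further 30 members matched to the table lay below the filter.

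Myogenic regulators and muscle structural genes moved in both directions. Of 16 measured, 8 fell, 2 rose and 6 did not pass the test (adjusted over the list alone, 8 fell and 4 rose). MYOD1 fell most, MYF5, another muscle-lineage regulator, fell from 265 to 115 FPKM (log2 -1.21), MEF2D fell by 1.13 on the log2 scale and CAV3, the muscle caveolin, fell by 0.98. The list did not stand apart from the other genes (median log2 -0.11, camera adjusted p = 0.227; adjusted p = 0.559 with an estimated correlation).

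Of 21 measured immediate early genes, which growth factors and stress induce within minutes, 16 fell, 4 rose and 1 did not pass the test, with the same counts adjusted over the list alone. The genes that rose, named after their values were seen, were FOS (log2 0.67), KLF4 (log2 0.63), DUSP6 (log2 0.42) and EGR1 (log2 0.28). DUSP1 and FOSL1 fell most, followed by ZFP36 (11.8 to 1.398 FPKM, log2 -2.77) and JUNB (25.05 to 3.61 FPKM, log2 -2.71). The median log2 change was -1.23 (camera adjusted p = 1.2e-04; adjusted p = 0.416 with an estimated correlation). Of 11 NF-kB and inflammatory cytokine genes, 6 fell, 2 rose and 3 did not pass, with the same counts adjusted over the list alone. LIF fell from 25.9 to 7.01 FPKM (log2 -1.86), NFKBIA, the inhibitor of NF-kB, fell by 1.76 on the log2 scale, BIRC3 fell by 0.99, and CXCL8 rose by 0.74. That list's median was -0.35 (camera adjusted p = 0.227; adjusted p = 0.458 with an estimated correlation).

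Stress and death pathways were mixed. Among 24 p53 targets and apoptosis genes, 17 fell, 2 rose and 5 did not pass (adjusted over the list alone, 17 fell and 3 rose). PMAIP1, which encodes the pro-apoptotic protein NOXA, rose from 11.8 to 45.3 FPKM (log2 1.89), whereas BTG2 (log2 -1.64), GADD45A (log2 -1.45) and BBC3, another pro-apoptotic gene (log2 -1.23), fell. The list holds anti-apoptotic genes as well, named after their values were seen. BCL2L1 (log2 -0.89), MCL1 (log2 -0.16) and XIAP (log2 -0.16) fell too, and BCL2 did not pass. The median was -0.22 (camera adjusted p = 0.0027; adjusted p = 0.307 with an estimated correlation). Of 20 unfolded protein and integrated stress response genes, 9 fell, 5 rose and 6 did not pass, with the same counts adjusted over the list alone. DDIT4 (log2 -2.66), PPP1R15A (log2 -1.82), HERPUD1 (log2 -1.62) and DDIT3, the stress factor CHOP (log2 -1.11), fell. The list's median was -0.15 (camera adjusted p = 0.227; adjusted p = 0.675 with an estimated correlation). Of 12 heat shock genes, 5 fell, 1 rose and 6 did not pass (adjusted over the list alone, 6 fell and 1 rose). DNAJB1 (log2 -1.12), BAG3 (log2 -0.64) and HSPA1A (log2 -0.51) fell and HSPA4L rose (log2 0.42), with a list median of -0.06 (camera adjusted p = 0.070; adjusted p = 0.307 with an estimated correlation). Of 18 NRF2 and oxidative stress genes, 5 rose, 5 fell and 8 did not pass (adjusted over the list alone, 6 rose and 5 fell). OSGIN1 (5.92 to 1.97 FPKM), HMOX1 (log2 -0.97) and GCLM (log2 -0.32) fell and SLC7A11 rose (log2 0.34). The median of that list was 0.01 and its mean -0.09, so they differ in sign (camera adjusted p = 0.879; adjusted p = 0.914 with an estimated correlation).

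EP300 and CREBBP both fell by less than 2-fold. EP300, which encodes the acetyltransferase p300, fell from 7.57 ± 0.81 to 4.63 ± 0.46 FPKM (log2 -0.65, limma adjusted p = 5.8e-04). CREBBP, which encodes its relative CBP, fell from 5.19 ± 0.36 to 4.09 ± 0.24 FPKM (log2 -0.31, limma adjusted p = 0.0035). The series title names both proteins as partners of DUX4. Of 21 acetyltransferase, deacetylase and bromodomain genes, 10 fell, 4 rose and 7 did not pass, with the same counts adjusted over the list alone; HDAC7 (log2 -0.71), BRD3 (log2 -0.58) and HDAC5 (log2 -0.52) fell as EP300 did, of which HDAC7 and HDAC5 encode deacetylases and BRD3 a bromodomain protein. The median was -0.14 (camera adjusted p = 0.070; adjusted p = 0.307 with an estimated correlation). Of 24 names of replication-dependent histone genes 18 were found, and 13 of these lay below the filter. The libraries were made with a poly(A) kit, which misses transcripts without a poly(A) tail. Of the 5 measured, which may not stand for the class, HIST1H2BK rose (21.9 to 24.4 FPKM, log2 0.15, limma adjusted p = 0.039) and 4 did not pass. Its call was lost with no filter (limma adjusted p = 0.129) and with most single libraries left out (log2 0.09 without the second doxycycline library), and adjusted over the list alone none rose or fell (median 0.11, camera adjusted p = 0.655; adjusted p = 0.729 with an estimated correlation).

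Of 30 cell cycle genes, 11 fell, 3 rose and 16 did not pass, with the same counts adjusted over the list alone. CDT1, a replication licensing factor (log2 -0.76), CCND1 (log2 -0.59), CDC20 (log2 -0.58) and CCNE1 (log2 -0.52) fell. The median was -0.05 (camera adjusted p = 0.034; adjusted p = 0.307 with an estimated correlation), and the call was lost without the second untreated library (adjusted p = 0.059), without the third doxycycline library (adjusted p = 0.079) and with voom (adjusted p = 0.057). Of 14 nonsense-mediated decay genes, 8 fell and 6 did not pass, with the same counts adjusted over the list alone. SMG9 (log2 -0.51), SMG5 (log2 -0.34), UPF3B (log2 -0.31) and CASC3 (log2 -0.31) fell, and the median was -0.18 (camera adjusted p = 0.021; adjusted p = 0.307 with an estimated correlation).

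Of 20 measured extracellular matrix and fibroblast markers, 14 rose, 1 fell and 5 did not pass (adjusted over the list alone, 15 rose and 1 fell). PDGFRA, a growth factor receptor of mesenchymal cells, rose from 0.165 to 5.59 FPKM (log2 3.19), and COL3A1 (log2 0.66), TCF4 (log2 0.64) and LUM (log2 0.42) rose by less than 2-fold. TCF4 is counted because the fixed list holds it, and whether it marks fibroblasts was not checked. PDGFRB, named after its value was seen, fell (log2 -0.19, limma adjusted p = 0.0098). The median was 0.14 (camera adjusted p = 3.5e-04; adjusted p = 0.307 with an estimated correlation). Of 14 interferon-stimulated genes, 5 rose, 2 fell and 7 did not pass, with the same counts adjusted over the list alone. IFIT2 (0.424 to 4.44 FPKM, log2 2.41), IFIT3 (log2 2.03) and the RNA sensor gene IFIH1 (0.4997 to 1.53 FPKM) rose and IRF1 fell (log2 -1.53). The median was 0.12 (camera adjusted p = 0.058; adjusted p = 0.416 with an estimated correlation), and the list passed the test without the first untreated library (adjusted p = 0.018), without the first doxycycline library (adjusted p = 0.025) and with a mean FPKM of at least 2 (adjusted p = 0.024). None of the 13 mitochondrially encoded genes passed the test, also adjusted over the list alone (median 0.11, camera adjusted p = 0.227; adjusted p = 0.757 with an estimated correlation); MT-CO2 was at 2803 and 2910 FPKM and MT-CO3 at 1773 and 1956 FPKM. Of 23 markers of other cell types 20 lay below the filter. Of the 3 measured, KRT18 fell (log2 -0.23, limma adjusted p = 0.046, lost with no filter and with most single libraries left out), TEK was at 8.48 and 9.27 FPKM (limma adjusted p = 0.059), and adjusted over the list alone 1 rose and 1 fell.

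**Figure D2:**
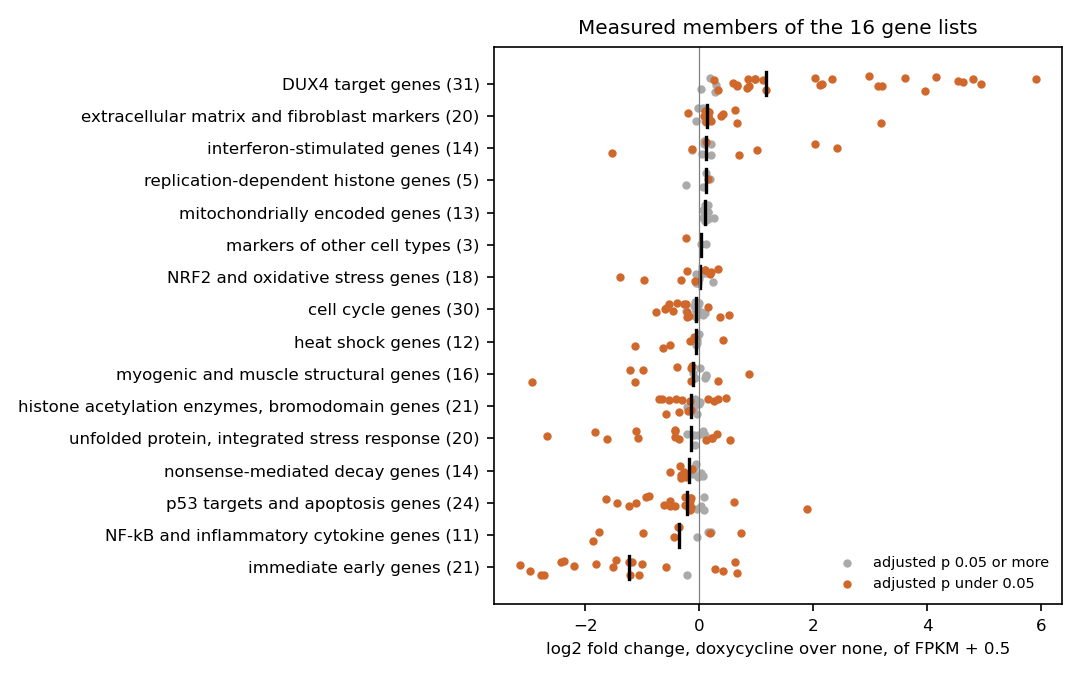
Log2 fold change (doxycycline over none, FPKM + 0.5) of each measured member of the 16 gene lists, with the number measured in brackets and a black line at the median. DUX4 target genes have a median of 1.18 and immediate early genes one of -1.23.

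The next question was whether genes near DUX4 binding sites rose. Of 1642 tested genes that the authors' deposited table classes as overlapping or within 10 kb of a DUX4 peak, 139 rose at least 2-fold (8.47%), against 173 of 10617 others (1.63%). ZSCAN4, DUXA, RFPL4B, ZNF705G, LINC01602 and PDGFRA were among those that rose, while OSR2, ZNF705A and PMAIP1 rose and were classed as over 50 kb away in the authors' deposited table. The odds ratio was 5.58 (95% interval 4.40 to 7.07; two-sided Fisher's exact test over genes, which are not replicates, p = 1.6e-42). In the class overlapping the gene start 29 of 222 genes rose (13.1%), and in the class over 50 kb away 164 of 10437 (1.57%). The genes within 10 kb as a set stood above the others in camera (p = 3.9e-12; p = 0.049 with an estimated correlation). Genes that fell were not fewer among them by this test, at 23 of 1642 (1.401%) against 225 of 10617 (2.12%), an odds ratio of 0.656 (95% interval 0.406 to 1.01, Fisher's exact p = 0.059). ID3, GADD45B and GADD45A fell and were classed as within 5 kb in the authors' deposited table. This odds ratio passed the test with a pseudocount of 0.1 (0.513, p = 5.7e-04), with voom (0.467, p = 4.4e-05), without the third untreated library (0.630, p = 0.033) and without the first doxycycline library (0.626, p = 0.042), by the same exact test. It lay nearer to 1 with a pseudocount of 1 (0.781, exact p = 0.329), with a mean FPKM of at least 2 (0.790, exact p = 0.354) and without the second doxycycline library (0.725, exact p = 0.182), and for genes overlapping the start it was 0.216 (exact p = 0.140). Gene starts were not matched to peaks directly, and the classes do not match distances to all DUX4 peaks: 45.5% of the chromosome span lay within 50 kb of a DUX4 summit, but 14.9% of tested genes were so classed.

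**Figure D3:**
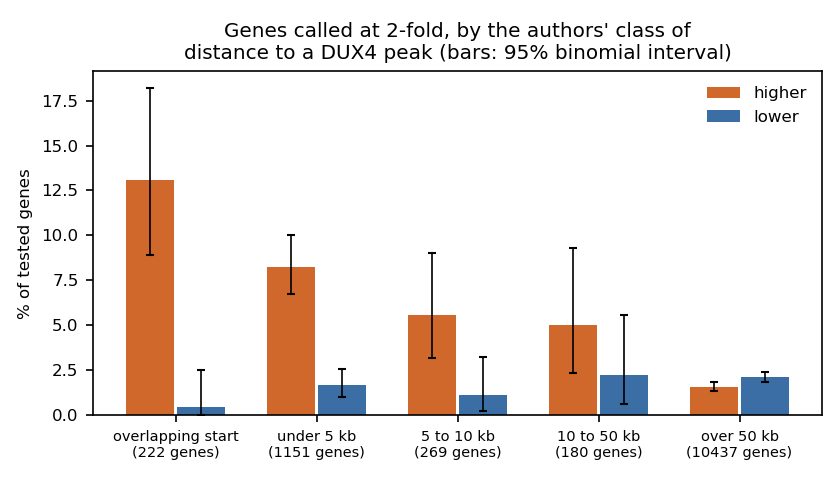
Share of tested genes that rose or fell at least 2-fold, by the authors' class of distance to a DUX4 peak, with 95% exact binomial intervals as bars. The share that rose is 13.1% in the class overlapping the gene start and 1.57% in the class over 50 kb.

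Among 959 genes within 10 kb whose DUX4 peak the authors' deposited table marks as overlapping a DNase site, 72 rose (7.51%) and 22 fell (2.29%). Among 683 whose peak it marks as outside such sites, 67 rose (9.81%) and 1 fell (0.146%). The share that fell differed (two-sided Fisher's exact p = 1.3e-04) and the share that rose did not pass (p = 0.106). The median untreated level was 7.61 FPKM in the first group and 4.83 FPKM in the second. A gene near 0 without doxycycline cannot be called lower, so the groups may differ in how many genes could fall. In the second group were ZSCAN4, DUXA, RFPL4B and ZNF705G, and in the first PDGFRA, IFIT3, ID3 and GADD45A.

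The third question was how H3K27ac peaks lie relative to DUX4 sites. The DUX4 list held 31613 peaks over 27.1 Mb. The 5 with the highest peak score lay, in hg19, on Un_gl000220 at 157057 to 160563 (score 3100), on chromosome 5 at 180899623 to 180901524 (3076), on Un_gl000220 at 113044 to 116716 (2843), on chromosome 3 at 104351146 to 104352800 (2422) and on chromosome 15 at 31318862 to 31320818 (2373). None of these 5 summits lay inside an H3K27ac peak of either dose. The scores are the authors', and these 5 were ranked within the DUX4 list. The summits on Un_gl000220, an unplaced sequence, had heights of 349 and 355 reads, against 124, 93 and 104 reads at the others. Whether they are single-copy DUX4 sites was not examined.

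The H3K27ac lists differed in shape between doses. Without doxycycline there were 136827 peaks over 92.8 Mb with a median width of 419 bp, and with it 170981 peaks over 43.6 Mb with a median width of 188 bp. Of the doxycycline peaks 81147 (47.5%) overlapped an untreated peak by at least 1 bp and 89834 (52.5%) did not, and of the untreated peaks 50823 (37.1%) overlapped a doxycycline peak and 86004 (62.9%) did not. Most doxycycline-only peaks (78.7%) had a score under 100, against 8.19% of untreated-only peaks, and with a score of at least 100 the doxycycline-only peaks numbered 19736 and the untreated-only peaks 97564, which turns their order. With equal numbers of peaks it turned as well (65997 and 90675). With equal covered length, chosen after the data were seen, 27.8% of doxycycline peaks and 80.9% of untreated peaks overlapped, which turns the order of the shares, and 4931 peaks were untreated-only. That setting kept only the 25868 highest-scoring untreated peaks, so it lowers the untreated-only count by construction. Scores of the lists may differ in scale, so the same limit may not be equally strict for both. With 1 library per antibody and dose these differences have no replicate check, and they compare 2 peak lists.

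DUX4 summits lay inside H3K27ac peaks more often than displaced summits did at both doses. Of the 31613 summits, 14.9% (95% exact binomial interval 14.5 to 15.3) lay inside an untreated peak and 9.29% (8.97 to 9.61) inside a doxycycline peak, against 4.09% and 2.44% of summits displaced by 50, 100 and 200 kb. The intervals cover counting error only. Summits inside peaks of both lists made up 5.42% (displaced 1.18%), of the doxycycline list only 3.87% (displaced 1.26%), of the untreated list only 9.52% (displaced 2.91%) and of neither 81.2% (displaced 94.7%). The order of the doses turned with equal covered length (7.71% untreated, 9.29% doxycycline) and with 1 kb windows (19.0% and 43.6%), both chosen after the data were seen. Equal covered length kept 25868 of 136827 untreated peaks and all doxycycline peaks, which can only lower the untreated share. Counted over the whole DUX4 peak the order of the doses turned too: 45.4% of DUX4 peaks touched a doxycycline H3K27ac peak (displaced 7.96%) and 24.7% an untreated one (displaced 7.34%). By that count 7839 DUX4 peaks (24.8%, displaced 4.51%) touched doxycycline H3K27ac alone and 1299 (4.11%, displaced 3.89%) untreated H3K27ac alone.

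The share of positions inside a doxycycline H3K27ac peak dipped at the DUX4 summit and was highest about 300 bp from it, in a profile chosen after the data were seen. It was 9.29% at the summit, 22.3% (22.0 to 22.7) at 300 bp, 11.5% at 1000 bp and 5.52% at 3000 bp. For untreated H3K27ac it was 14.9%, 17.5%, 11.96% and 6.79% at the same distances. Within 500 bp of the summit, sites touching doxycycline H3K27ac alone made up 16.6% (15.8 to 17.4) of the 7904 sites with the lowest DUX4 scores and 38.9% (37.8 to 40.0) of the 7903 with the highest, and sites touching untreated H3K27ac alone 5.07% and 2.19%. Sites touching untreated H3K27ac at all, alone or not, rose with the score as well, from 21.0% to 30.1%. Those touching doxycycline H3K27ac at all rose from 32.5% to 66.7%.

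**Figure D4:**
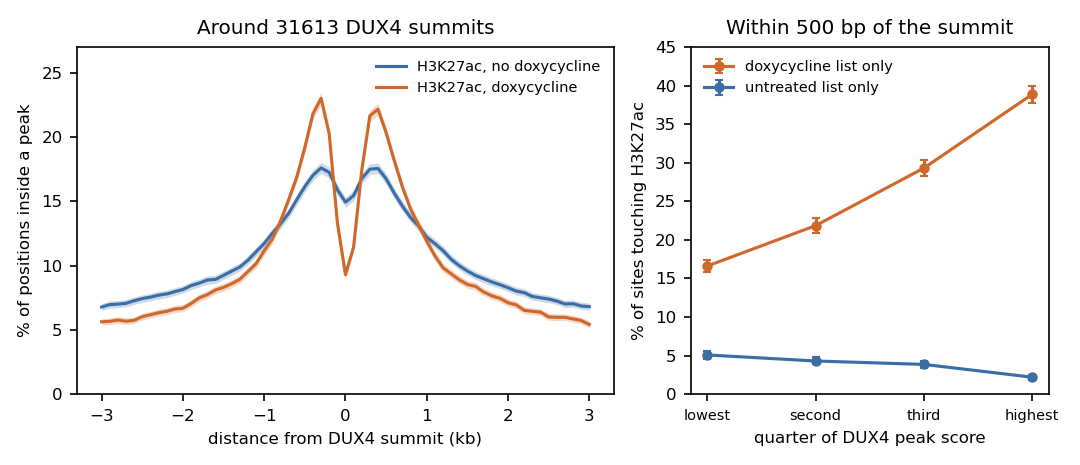
Left, share of positions inside an H3K27ac peak by distance from the DUX4 summit in kb, with shaded 95% exact binomial intervals. Right, share of DUX4 sites touching H3K27ac of one list only within 500 bp, in 4 groups of sites by DUX4 peak score, rising from 16.6% to 38.9% for the doxycycline list.

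Of 89834 doxycycline-only H3K27ac peaks, 992 held a DUX4 summit (1.10%, displaced 0.399%). Of doxycycline peaks that overlapped an untreated one 2.38% did (displaced 0.507%), of untreated-only peaks 0.844% (displaced 0.600%) and of untreated peaks that overlapped a doxycycline one 7.52% (displaced 1.48%). In windows of 1 kb at the peak midpoints, chosen after the data were seen, 12.4% of doxycycline-only windows (displaced 1.95%) and 1.45% of untreated-only windows (displaced 1.30%) held a summit. With a score of at least 100 for H3K27ac and DUX4 peaks alike, which left 12438 summits, 1.39% of doxycycline-only peaks (displaced 0.266%) and 0.458% of untreated-only peaks (displaced 0.268%) held a summit.

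The authors' deposited table gave 699 genes that rose and 360 that fell at least 2-fold with its adjusted p under 0.05. Those counts are over 18657 genes, of which 6398 lay below the filter of the limma test, while limma tested 12289. Of the 312 genes that rose and 249 that fell by limma, 297 and 237 had the same call in the authors' deposited table. The rest of the authors' 699 and 360 genes were not called by limma. Across the 12259 genes in both, Pearson's r between the log2 fold changes of limma and of the authors' deposited table was 0.974 and the sign was the same for 99.7%. For ID1 the authors' deposited table gave a log2 fold change of -2.25, smaller than the -3.84 of limma. For PMAIP1 the authors' deposited table gave 1.92, against 1.89 by limma.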

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

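The tests in this part were chosen only after the result was seen, except the test of where silent genes lie relative to DUX4 peaks.

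Of the genes below the expression filter, which the comparisons do not use, 565 were listed at 0 in every untreated library and above 0 in every doxycycline library, against 70 with the reverse pattern. Library depth was argued against: the shallowest doxycycline library held 1.022 times the reads of the deepest untreated one but listed 1.069 times as many genes above 0, while 1.12 times the reads gave 1.016 times the genes between untreated libraries. A rise at silent genes with no regard to DUX4 peaks was argued against too, for the 188 listed in the authors' deposited table. Of them 68 (36.2%) were classed up to 10 kb from a DUX4 peak, against 637 of 6210 other genes below the filter (10.3%). The odds ratio was 4.956 (95% interval 3.58 to 6.81, Fisher's exact p = 2.0e-20). Most of the 188 were not so classed, and 4 genes in that table had the reverse pattern, so a rise away from these peaks as well stays open. A candidate explanation for the genes classed near a DUX4 peak is activation of silent genes near DUX4 sites, which stays open for the genes outside that table. Doxycycline itself was not tested apart from DUX4.

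DUX4 sites had doxycycline-only H3K27ac beside them. A difference between the lists in peak calling alone was argued against by the whole-peak count. DUX4 peaks touching doxycycline H3K27ac alone stood at a ratio of 6.035 to those touching untreated H3K27ac alone, against 1.09 to 1.22 in displaced sets. At the summit itself there was no such excess. Summits in doxycycline peaks alone stood at 3.07 times their displaced share and those in untreated peaks alone at 3.27 times. Signal highest at the summit itself was argued against, since 9.287% of summits lay inside a doxycycline peak against 22.3% of positions 300 bp away. Shares were alike on both sides, 23.0% at -300 bp and 21.7% at +300 bp. Untreated peaks dipped at the summit as well (14.9% against 17.5% at 300 bp). Signal centred on the site with a dip at the summit therefore stays open. Acetylation that goes with DUX4 binding may account for the doxycycline-only H3K27ac beside these sites. The share of sites with it within 500 bp was 38.87% among sites with the highest DUX4 scores and 16.6% among those with the lowest. Sites with untreated H3K27ac within 500 bp made up 30.1% and 21.0% of the same groups, so the score also follows acetylation present without doxycycline. With 1 library per dose, a difference between libraries that follows open or bound chromatin stays open.

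Changes were smaller in the third doxycycline library, set against the mean of the other doxycycline libraries on the log2 scale. Of the 97 genes that rose over 4-fold 95 lay below that mean, and 36 of 36 that fell over 4-fold lay above it. Scaling of the library was argued against, since the median difference from that mean was 0.7629 for genes that fell over 4-fold and -0.31 for genes that rose over 4-fold. Dilution with untreated RNA stays open: the share needed was 21.99% (interquartile range 15.7 to 27.4) by the genes that rose over 4-fold and 11.99% (10.6 to 13.1) by those that fell over 4-fold, but these ranges overlapped for all genes called, at 21.6% (14.6 to 27.02) and 15.4% (12.3 to 18.9). A lower or later induction in that library stays open too and was not tested, since the DUX4 row does not register it. Without this library 332 genes rose and 300 fell.

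For the genes that rose or fell at least 2-fold, the 10 splits of the 6 libraries are too few for a share under 0.05: 1 split, the real one, gave 561 genes and the highest of the others gave 0.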

How the results depend on the processing

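Voom, equal covered length, 1 kb windows and the alternatives of the whole-peak count were chosen only after the data were seen. No named gene or list past its test changed direction under the alternatives run. The order of the doses turned for DUX4 summits in H3K27ac (whole DUX4 peaks, equal covered length, 1 kb windows), for summits in one list alone (the same settings), for peaks in one list alone (score of at least 100, equal numbers) and for overlap shares (equal covered length). The cause of each change below was not tested unless its construction shows it. The genes that rose numbered 238 (pseudocount 1) to 460 (voom) and those that fell 185 to 394 (voom) at 2-fold; with a mean FPKM of at least 2, which tests fewer genes, 187 rose, and with no fold minimum 2834 rose and 3389 fell. Leaving out 1 library gave 275 to 338 that rose and 211 to 300 that fell. For 72 named genes, 984 of 1001 values kept their side of the threshold, though MT-CO2 and MT-CO3, not past the test, changed sign without the second untreated library; 15 lost the call, in HIST1H2BK and KRT18, and 2 gained it, in TEK. The median of DUX4 targets was 0.67 with no filter, 3.06 with a mean FPKM of at least 2 and 1.99 with voom. Medians of lists not past the test changed sign for myogenic genes (0.0015 with no filter), NRF2 genes (-0.0133 with no filter, -0.0123 with a mean FPKM of at least 2, -0.0110 without the first doxycycline library) and mitochondrial genes (-0.0470 without the second untreated library). With an estimated correlation the calls were lost for DUX4 targets (1.18), p53 (-0.22), immediate early (-1.23), cell cycle (-0.0541), nonsense-mediated decay (-0.18) and matrix genes (0.14). With fry, lists passed that had not: myogenic (-0.11), unfolded protein (-0.15), heat shock (-0.0635), acetyltransferase, deacetylase and bromodomain (-0.14), interferon (0.12) and NF-kB genes (-0.35). With no filter heat shock (-0.05) and acetyltransferase, deacetylase and bromodomain genes (-0.13) passed, with a mean FPKM of at least 2 interferon genes did (0.13), and with voom cell cycle genes did not (-0.0502). Leaving out 1 library, the medians ranged from 0.0606 to 0.145 for interferon and from -0.0689 to -0.0472 for cell cycle genes, with calls changed in 2 sets each. The odds ratio of genes that fell near DUX4 was 0.513 (pseudocount 0.1), 0.467 (voom), 0.781 (pseudocount 1), 0.790 (mean FPKM of at least 2), 0.216 (overlapping the start) and 0.626 to 0.725 with 1 library left out; that of genes that rose was 4.41 (voom) to 6.24 (overlapping the start).

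With the replicate number as a block, 314 genes rose and 249 fell; libraries with the same number did not deviate together (correlations -0.051, -0.021 and -0.033).

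With a score of at least 100 for all lists (12438 summits), doxycycline-only H3K27ac peaks numbered 19736 and untreated-only peaks 97564, 67.7% of doxycycline peaks overlapped an untreated one and 23.9% the reverse; summits inside untreated peaks were 16.02%, doxycycline peaks 7.13% (displaced 1.47%), doxycycline alone 2.90% and untreated alone 11.8%; summits were held by 1.39% of doxycycline-only and 0.458% of untreated-only peaks; whole DUX4 peaks touched doxycycline alone in 19.1% and untreated alone in 6.30%. With equal numbers of peaks, 65997 were doxycycline-only and 90675 untreated-only, and the other values in this order were 51.8% and 33.7%; 8.60% inside doxycycline peaks (displaced 2.14%) and 3.42% in doxycycline alone; 1.30% and 0.947%; 21.4% and 4.98%. With equal covered length, untreated-only peaks numbered 4931, and overlaps were 27.8% and 80.9%; summits inside untreated peaks 7.71% (displaced 1.76%), doxycycline alone 5.65%, untreated alone 4.07%; held by 1.37% and 1.26%. With 1 kb windows, overlaps were 53.3% and 52.9%; inside untreated 19.0% (displaced 5.51%), doxycycline 43.6% (displaced 7.47%), doxycycline alone 28.7%, untreated alone 4.11%; held by 12.4% and 1.45%. With overlap over 50% of the smaller peak, overlaps were 44.3% and 34.1%, and 1.07% of untreated-only peaks held a summit. With whole DUX4 peaks, 24.7% touched untreated (displaced 7.37%) and 45.4% doxycycline (displaced 7.94%), 24.8% doxycycline alone and 4.11% untreated alone; these displaced shares centre a window of the peak's width on the displaced summit, while the 7.34% and 7.96% of the report displace the peak itself. Random placement gave 3.16% (untreated) and 1.57% (doxycycline).

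Not run, for want of hg19 gene starts, were gene distances of 1 kb and 100 kb, a stricter score and equal numbers for expression near DUX4, and expression by promoter H3K27ac with its alternatives. Recovered depths of 27417323 to 33071808 reads limit genes near 0; the depth of the immunoprecipitated libraries is unknown.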

Other observations

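The gene groups in this part were chosen only after the values were seen, so their counts are descriptions, and no explanation was tested.

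Genes that BMP and TGF-beta signalling induce fell widely. Of 16 measured, 14 fell and 2 rose, with a median log2 change of -1.10. Beside ID1, ID3 and KLF10, NOG, which encodes the BMP antagonist noggin, fell from 87.8 to 18.3 FPKM (log2 -2.28), ATOH8 fell by 1.89 on the log2 scale and the inhibitory SMAD7 by 1.17. BAMBI, a decoy receptor gene, rose (log2 1.90), as did SMAD9 (log2 0.47). Of 12 target genes of the transcriptional co-activator YAP, 11 fell and 1 rose, with a median of -1.52. CYR61 fell from 516 to 99.1 FPKM (log2 -2.43) and ANKRD1 from 994 to 270 FPKM (log2 -1.94), and AMOTL1 rose (log2 0.41). EDN1 is counted in this group as well. CYR61 and CTGF are also among the immediate early genes that fell, so the falls of these groups are not separate.

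Most feedback inhibitors of MAP kinase signalling fell, but members of both groups below rose. Of 8 MAP kinase phosphatase genes 6 fell and 2 rose (median -1.30), with DUSP4 at log2 -1.99 and DUSP6 at 0.42. DUSP1, DUSP5 and DUSP6 are in the immediate early list too. Of 6 Sprouty and SPRED genes 4 fell and 2 rose, with SPRY4 at log2 -2.15 and SPRY2 at 1.24.

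In 7 multicopy families, chosen after their rise was seen, each measured row rose: 3 of 6 ZNF705, 3 of 4 ZSCAN5, 5 of 8 SSU72 pseudogene, 5 of 23 PRAMEF, 5 of 9 TRIM43 and TRIM64, 2 of 28 FAM90A and 2 of 10 PRELID3B pseudogene rows. The other rows lay below the filter, which is set on the mean of all libraries and so favours rows near 0 without doxycycline that rose. The members of the DUX4 target list that did not pass the test also belong to multicopy families: MBD3L2 (log2 0.04, limma adjusted p = 0.752), MBD3L3 (log2 0.29, limma adjusted p = 0.222), TRIM49 (log2 0.18, limma adjusted p = 0.264) and TRIM53AP (log2 0.28, limma adjusted p = 0.224). Reads that fit several copies may have been counted for more than 1 row, so the rows of a family may not be independent. Among the 15 genes that rose over 16-fold, the untreated level was 0.202% (PRELID3BP6) to 4.98% (ZSCAN5D) of the doxycycline level, with ZSCAN4 at 1.54% and DUXA at 2.75%.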
